A study of Homo sapiens with 12 samples.

How the data were processed

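Normal human epidermal melanocytes are the pigment-making cells of the skin. Per the labels' protocols, commercial primary cells of a single batch were grown in serum-free medium, used at passage 3 and, once confluent, given cytokines or left without. Tumor necrosis factor (TNF, at 10 ng/ml) and interleukin-17 (IL-17, at 20 or 200 ng/ml) were given alone or together. The 6 treatments (control, TNF, each IL-17 dose, and TNF with each IL-17 dose) were each measured after 24 h and after 48 h, with 1 array per treatment and time and 12 arrays in all. Total RNA was extracted on columns, amplified in a single round and labelled with biotin, per the labels' protocols. Groups, doses and times came from the labels of each array.

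The deposited table holds 54675 Affymetrix probe sets per array as log2 values, which the authors made with GCRMA, per the submitters' processing notes. GCRMA corrects the background by the probes' base content, normalizes quantiles between arrays and summarises the probes of a set. Its version and settings are not given in the sources used here. The deposited log2 values had a floor, at which 32.77 to 33.69% of probe sets stood in each array. Array medians lay between 2.924 and 2.966, maxima between 15.24 and 15.51, and 42.94 to 43.6% of probe sets reached a log2 value of 4. A quantile step forces the arrays to one distribution, so a change in the total amount of RNA per cell cannot be seen in these values. For arrays, the number of arrays limits the precision.

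Of the probe sets, 62 were array controls, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none in the platform annotation given with the data. Symbols of 41037 probe sets were updated through Entrez gene identifiers, and 2 list members were matched under older symbols. Controls, probe sets with several genes or none, and 59 further probe sets for genes that can tell one donor from another were left out. A probe set with several genes names none of them, so some well-known members of the gene lists were not analysed here. Genes entered the tests where a probe set reached a log2 value of 4 in at least 2 arrays. The probe set with the highest mean over the 12 arrays stood for a gene with several. Of 19740 genes with a usable probe set, 11319 were tested. No column of the table was left unused.

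Differences were tested with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package for reading. The fit had 1 term per treatment and a time term, and eBayes without a trend moderated the variances. Benjamini-Hochberg adjustment was made within each comparison, at an adjusted p under 0.05. No treatment had a second array at the same time. The spread was therefore how far treatment effects differed between the times, with 5 residual degrees of freedom and 3.2 prior ones. Terms for a TNF or IL-17 effect that differs by time left 4 residual degrees of freedom. Because all cultures came from 1 batch of cells, the p-values measure only the spread between these cultures, which may be technical.

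The comparisons were TNF against control, IL-17 (mean of both doses) against control, TNF plus IL-17 (mean of both doses) against control, and TNF plus IL-17 against TNF. The interaction was the effect of IL-17 with TNF minus its effect without TNF, on the log2 scale. IL-17 dose was 200 against 20 ng/ml over arrays with and without TNF. Further comparisons were all TNF arrays against their matches without TNF, all IL-17 arrays against those without, 48 h against 24 h, and the by-time terms. Several of them use the same control arrays, so overlaps and correlations between comparisons were not computed. Errors after log2 changes are standard errors from the fit. Where every array on the lower side of a comparison stood under a log2 value of 4, the fold is a bound, set with that side at 4 and the other as measured, and is written "at least". No bound is given where this leaves no difference.

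Gene lists were fixed before the data were examined. They held pigmentation genes, growth-associated chemokines and cytokines, NF-kB targets, IL-17 response genes, interferon response genes, antigen presentation by MHC class I and class II, cell cycle genes, apoptosis regulators, matrix and protease genes, dedifferentiation and adhesion genes of melanocytes, cytokine receptors and adaptors, cholesterol synthesis, the unfolded protein response, the oxidative stress response and p53 targets. Marker lists of fibroblasts, keratinocytes, endothelial cells and immune cells stood for other cells that a culture could hold. Lists of at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and 8 comparisons together. Camera with an estimated correlation and fry were run beside it. The growth and IL-17 response lists share 5 tested members, apoptosis regulators and p53 targets share 3, and other pairs share at most 1.

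The rule for named genes was also fixed beforehand. It took up to 8 genes with the largest rise and 8 with the largest fall among those past the test whose matched differences all went that way by at least 0.01, or the 5 with the smallest p where fewer than 5 passed. The 0.01, a tolerance for values at the floor, was set after the data were seen. The rule also took up to 4 members of each list by smallest p, and a fixed set of pigment and cytokine genes in the comparisons of TNF, IL-17, both and the interaction.

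The tests were tried on simulated data built on the 11319 real genes, with 50 changed genes per size. At a log2 change of 1, the share recovered was 90% for TNF alone, 96% for IL-17 alone, 88% for TNF plus IL-17, 90% for adding IL-17 to TNF and 78% for the interaction. At a log2 change of 0.5 it was 30% for TNF alone, 42% for IL-17 alone and 8% for the interaction. False calls made up 1.82 to 6.54% of calls. The simulated errors were independent between genes and arrays and had no floor. These shares therefore do not cover genes that move together or lie at the floor.

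Alternatives chosen beforehand were no filter, a stricter filter at a log2 value of 6, the mean of a gene's probe sets, a further quantile normalization, a damped log2 with 32 added to linear values, and eBayes with a trend and robust variances. Further ones were doses pooled, no time term, each time alone with the doses pooled, only the treatments compared, a 2-fold minimum, array weights, additivity of linear values and leaving out each array. Chosen after seeing the data were each IL-17 dose alone, linear additivity over all genes, and the difference between the 3' and 5' ACTB control probe sets, a sign of RNA quality, as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.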

Results

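Gene expression was measured in primary human epidermal melanocytes after 24 and 48 h with TNF, IL-17, both or neither. TNF and IL-17 are inflammatory cytokines found together in psoriatic skin. The study's title asks whether they act in synergy on cytokines tied to growth while lowering pigment production. Each of the 6 treatments had 1 array at each time, and 11319 genes were tested. Pairwise correlations of the 12 arrays ran from 0.9401 to 0.997. On the first principal component, with 60.2% of the variance, control arrays lay at -14.95 (24 h) and -41.25 (48 h), TNF arrays at 27.08 and 4.34, and TNF with the higher IL-17 dose at 44.87 and 25.5. Each cytokine effect below is the mean over both times, with its standard error. All genes named for the size of their change went the same way in every matched pair of arrays.

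**Figure D1:**
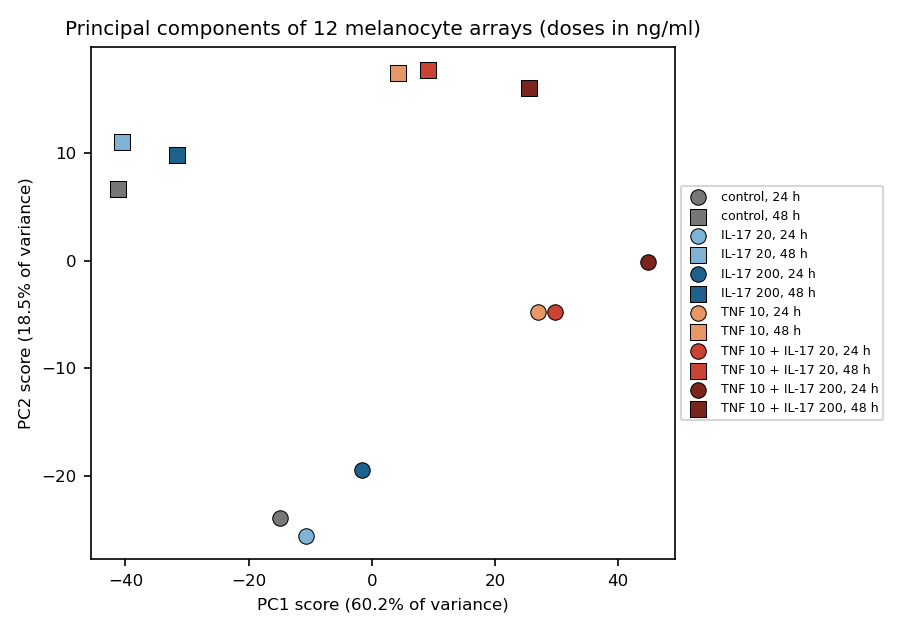
Principal components of the 12 arrays over the tested genes, with the first component (60.2% of the variance) on the x axis and the second (18.5%) on the y axis; each point is 1 array, coloured by treatment and shaped by time. Arrays with TNF lie to the right of the arrays without TNF of the same time.

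TNF alone turned on chemokine, cytokine and interferon-type genes in melanocytes and lowered a part of the pigment program. IL32, an inflammatory cytokine, rose at least 50.9-fold (6.47 ± 0.19 log2 units), and IL1B, the interleukin-1 beta gene, at least 20.3-fold (5.34 ± 0.57). The leukocyte attractants CCL5 (4.93 ± 0.25, 30.5-fold), CXCL11 (4.53 ± 0.42, 23.2-fold), CXCL10 (4.34 ± 0.31, 20.3-fold), CCL20 (3.72 ± 0.67, 13.2-fold) and CCL2 (3.63 ± 0.11, 12.4-fold) rose as well, and so did IL6 (2.35 ± 0.24, 5.09-fold). CSF3, the granulocyte growth factor, rose at least 3.97-fold (2.53 ± 0.52, adjusted p = 0.0177) from a level near the floor. Its call held in 15 of 25 alternatives (adjusted p from 0.000236 to 0.609). It was lost, among others, with the ACTB difference in the fit (2.69 ± 0.78, 0.138), without the 24 h control (2.09 ± 0.65, 0.135) and without either TNF array (2.68 ± 0.70, 0.0828, and 2.37 ± 0.70, 0.11). The CCL20 call held in 17 of 25 (adjusted p up to 0.199) and was lost, among others, without the 48 h control (3.25 ± 0.85), without the 48 h TNF array (3.15 ± 0.83) and with the ACTB difference (3.86 ± 1.01). RGS5, a regulator of G-protein signals, rose at least 9.38-fold. The largest falls were in ADCY2, an adenylate cyclase (-2.46 ± 0.31), IL16 (-2.38 ± 0.22), the potassium channel gene KCNJ13 (-2.32 ± 0.23), the melanocyte channel gene TRPM1 (-2.26 ± 0.28), SLC27A3 (-2.19 ± 0.14) and ITGA9 (-2.18 ± 0.16). PMP2, a lipid-binding myelin protein, was at least 4.41-fold and FXYD3 at least 2.19-fold lower, both under a log2 value of 4 with TNF.

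Of 19 growth-associated chemokines and cytokines tested, 16 rose and none fell with TNF (17 adjusted over the list alone), with a median of 1.70. CXCL8 rose by 1.83 ± 0.23, CXCL3 by 1.36 ± 0.16, CXCL2 by 1.04 ± 0.10 and CXCL1 by 0.48 ± 0.09. The CXCL1 call held in 17 of 25 alternatives (adjusted p up to 0.633) and was lost, among others, without the 24 h control (0.40 ± 0.11), without either TNF array (0.48 ± 0.12 and 0.47 ± 0.12) and with the ACTB difference in the fit (0.41 ± 0.13). Of 28 NF-kB targets, 21 rose (26 adjusted over the list alone), among them the adhesion molecule ICAM1 (2.96 ± 0.09), the transcription factor IRF1 (2.52 ± 0.11) and the secreted pattern receptor PTX3 (2.77 ± 0.13). Of 38 interferon response genes, 28 rose (33 adjusted over the list alone), including the tryptophan-degrading enzyme IDO1 (3.44 ± 0.26) and the antiviral gene RSAD2 (1.78 ± 0.13). Of 19 genes of MHC class I presentation, 10 rose (10 adjusted over the list alone), such as the proteasome subunit PSMB10 (1.28 ± 0.17) and the peptide transporter TAP1 (0.59 ± 0.09). Of 14 IL-17 response genes, 7 rose (7 higher and 1 lower adjusted over the list alone), among them the complement gene C3 (1.84 ± 0.21), while NFKBIZ, an IL-17-responsive regulator, stood at 0.29 ± 0.14 (adjusted p = 0.237). These lists moved as groups in limma's camera, with adjusted p of 5.46e-18, 8.66e-26, 5.94e-27, 5.77e-08 and 6.74e-05. With an estimated correlation they held at much weaker adjusted p, 0.0117, 0.0117, 0.0117, 0.0447 and 0.0374 in that order.

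Of 21 dedifferentiation genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone). The list's camera adjusted p was 1.56e-08, and 0.0117 with an estimated correlation. CCN1, a matricellular signal protein, rose by 2.26 ± 0.16, the collagen cross-linker LOXL2 by 1.83 ± 0.19, the guidance factor SLIT2 by 1.72 ± 0.18 and the Wnt ligand WNT5A by 1.35 ± 0.15. Of 13 adhesion genes, 2 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.365): E-cadherin (CDH1) fell by 1.47 ± 0.15 and N-cadherin (CDH2) rose by 1.06 ± 0.21. Of 26 apoptosis regulators, 5 rose and 1 fell (9 and 1 adjusted over the list alone). The death ligand TNFSF10 rose by 2.58 ± 0.11 and the death receptor FAS by 0.61 ± 0.11, and the list had a camera adjusted p = 0.00323 (adjusted p = 0.106 with an estimated correlation). Of 26 matrix and protease genes, 5 rose and 2 fell (10 and 3 adjusted over the list alone), with the laminin chain LAMB3 at 1.26 ± 0.14 and LAMA4 at -1.01 ± 0.23. That list's camera adjusted p was 0.000253 (adjusted p = 0.122 with an estimated correlation). Of 42 cell cycle genes, only the regulator E2F1 passed (0.69 ± 0.15), and none did adjusted over the list alone (camera adjusted p = 0.0457, and adjusted p = 0.743 with an estimated correlation).

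Of the remaining lists, pigmentation genes aside, fibroblast markers had a camera call at the preset correlation with TNF alone. Class II presentation (10 tested, camera adjusted p = 0.803) had 2 genes higher, the protease CTSS (2.18 ± 0.17) and the invariant chain CD74 (0.68 ± 0.15); its median was -0.17 and its mean 0.12. Among 22 cytokine receptors and adaptors (adjusted p = 0.963), IL6R fell by 1.05 ± 0.14 and TNFRSF21 by 0.98 ± 0.25. Among 17 cholesterol synthesis genes (adjusted p = 0.759), ACAT2 fell by 1.48 ± 0.13 and the sterol carrier STARD4 rose by 0.65 ± 0.16. The unfolded protein response (24 tested, adjusted p = 0.263) had 1 gene higher, ATF3 (1.20 ± 0.11). The oxidative stress response (21 tested, adjusted p = 0.435) had GPX4 (0.66 ± 0.13) and SOD2 (0.35 ± 0.08) higher. Among 20 p53 targets (adjusted p = 0.736), 2 rose and 2 fell, with SESN1 at -0.60 ± 0.13. Of 14 fibroblast markers, 5 rose, with LOX at 1.29 ± 0.18 and PDGFRA at 0.75 ± 0.11 (camera adjusted p = 0.00302, and adjusted p = 0.0996 with an estimated correlation). Of the immune cell markers, 3 of 20 were tested and LCP1 rose by 0.92 ± 0.20.

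In all, 1311 genes changed with TNF alone (709 higher, 602 lower) by limma with Benjamini-Hochberg adjustment, 315 of the higher and 107 of the lower by at least 2-fold. The 3' minus 5' difference of the ACTB control probe sets, a sign of RNA quality, was 0.36 ± 0.16 higher with TNF than in the control. The same difference of the GAPDH control probe sets was 0.06 ± 0.05. In the other comparisons, by-time terms aside, the GAPDH difference ran from -0.09 ± 0.06 (interaction) to 0.05 ± 0.04 (IL-17 alone). It did not show the shifts of ACTB given here and below. The count was 329 with the ACTB difference in the fit. Leaving out a TNF or control array also lowered the count.

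IL-17 alone gave smaller differences, and none passed the test when both doses were averaged (0 genes by limma, 550 at an unadjusted p under 0.05). The smallest p belonged to the sulfatase gene SULF1 (0.77 ± 0.08) and the neuronal adhesion gene LRRN1 (1.36 ± 0.14), both with an adjusted p of 0.0576. CHDH (-0.82 ± 0.09), the hyaluronan-binding TNFAIP6 (0.73 ± 0.09) and CXCL2 (0.74 ± 0.09) followed at 0.0607. CXCL2 passed in 4 of 27 alternatives: the stricter filter (adjusted p = 0.0401), damped log2 (0.0363), a variance trend (0.000981) and 200 ng/ml alone (0.00603). CXCL1 and CXCL3 passed in 2 of 27 each, with a variance trend and at 200 ng/ml alone. CXCL3 stood at 0.83 ± 0.14, IL6 at 0.92 ± 0.21, CXCL8 at 0.69 ± 0.20, CXCL1 at 0.35 ± 0.08, NFKBIZ at 0.41 ± 0.12 and CCL20 at 1.02 ± 0.58. CSF3, under a log2 value of 4 in the controls, was at least 2.48-fold higher on average (adjusted p = 0.514) and passed without the 48 h array of 200 ng/ml IL-17 (2.40 ± 0.14, adjusted p = 0.007). Of these cytokines and NFKBIZ, CXCL1 lay above control in 3 of 4 matched pairs and the others in 4 of 4. As a group, the growth list was higher (19 tested, median 0.53, camera adjusted p = 2.99e-20), and 11 members rose adjusted over the list alone. The IL-17 response list was higher too (14 tested, median 0.41, adjusted p = 6.31e-10), with 8 members higher adjusted over the list alone. Both held with an estimated correlation, at a camera adjusted p of 0.0117 each. The count of 0 was 2 without the 48 h control and 1 without the 48 h array of 200 ng/ml IL-17.

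Other lists shifted with IL-17 alone at the preset correlation and were lost with an estimated one. They were NF-kB targets (3 higher adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), class II presentation (5 lower adjusted over the list alone; adjusted p = 0.0767 with an estimated correlation) and dedifferentiation genes (3 higher adjusted over the list alone; adjusted p = 0.104 with an estimated correlation). Cell cycle genes (adjusted p = 0.527 with an estimated correlation) and pigmentation genes (adjusted p = 0.241 with an estimated correlation) were lost likewise, with none past the test adjusted over the list alone. The other lists had camera adjusted p of 0.0726 (interferon response) or more. HLA-DQB1 stood at -0.51 ± 0.09 and HLA-DRA at -0.44 ± 0.09. MITF (0.04), TYR (0.00), TYRP1 (0.08), PMEL (-0.05) and MLANA (0.00) lay within 0.08 of control. The ACTB 3' minus 5' difference was 0.37 ± 0.14 higher with IL-17. Taken separately after the data were seen, 200 ng/ml IL-17 changed 21 genes (19 higher, 2 lower) and 20 ng/ml changed 0 by limma, with 256 at an unadjusted p under 0.05. At 200 ng/ml CXCL2 rose by 1.20 ± 0.10, CXCL6 by 1.48 ± 0.17, CXCL3 by 1.28 ± 0.16, CCL2 by 1.05 ± 0.11, CXCL1 by 0.63 ± 0.09 and PTX3 by 1.35 ± 0.13.

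With TNF plus IL-17, all 19 growth-associated chemokines and cytokines tested were above control (19 adjusted over the list alone, median 1.88, camera adjusted p = 3.17e-18). IL1B rose at least 99.7-fold (7.64 ± 0.49) and CSF3 at least 22.2-fold (5.01 ± 0.45). CCL5 rose by 4.78 ± 0.22, CCL20 by 4.28 ± 0.58, CCL2 by 3.79 ± 0.10, the epidermal growth factor family member EREG by 3.07 ± 0.19 and IL6 by 2.86 ± 0.21. CXCL8 rose by 1.88 ± 0.20, CXCL3 by 1.67 ± 0.14, CXCL2 by 1.31 ± 0.09 and CXCL1 by 0.63 ± 0.08. The CCL20 call held in 25 of 27 alternatives and the CXCL1 call in 24 of 27. Both were lost with the ACTB difference in the fit (4.45 ± 1.12, adjusted p = 0.0791, and 0.54 ± 0.14, adjusted p = 0.091). Other large rises were RGS5 (at least 31.8-fold), IL32 (at least 26.9-fold), the chemokine receptor CXCR4 (4.89 ± 0.46, 29.6-fold), TNFAIP2 (4.58 ± 0.18, 24-fold) and CXCL11 (4.30 ± 0.36). The largest falls were ADCY2 (-3.05 ± 0.27), ITGA9 (-2.79 ± 0.13), SLC45A2 (-2.76 ± 0.10), TRPM1 (-2.71 ± 0.24), KCNJ13 (-2.70 ± 0.20), IL16 (-2.61 ± 0.19) and the proton pump subunit ATP6V0D2 (-2.56 ± 0.18). PMP2 was at least 4.41-fold lower.

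**Figure D2:**
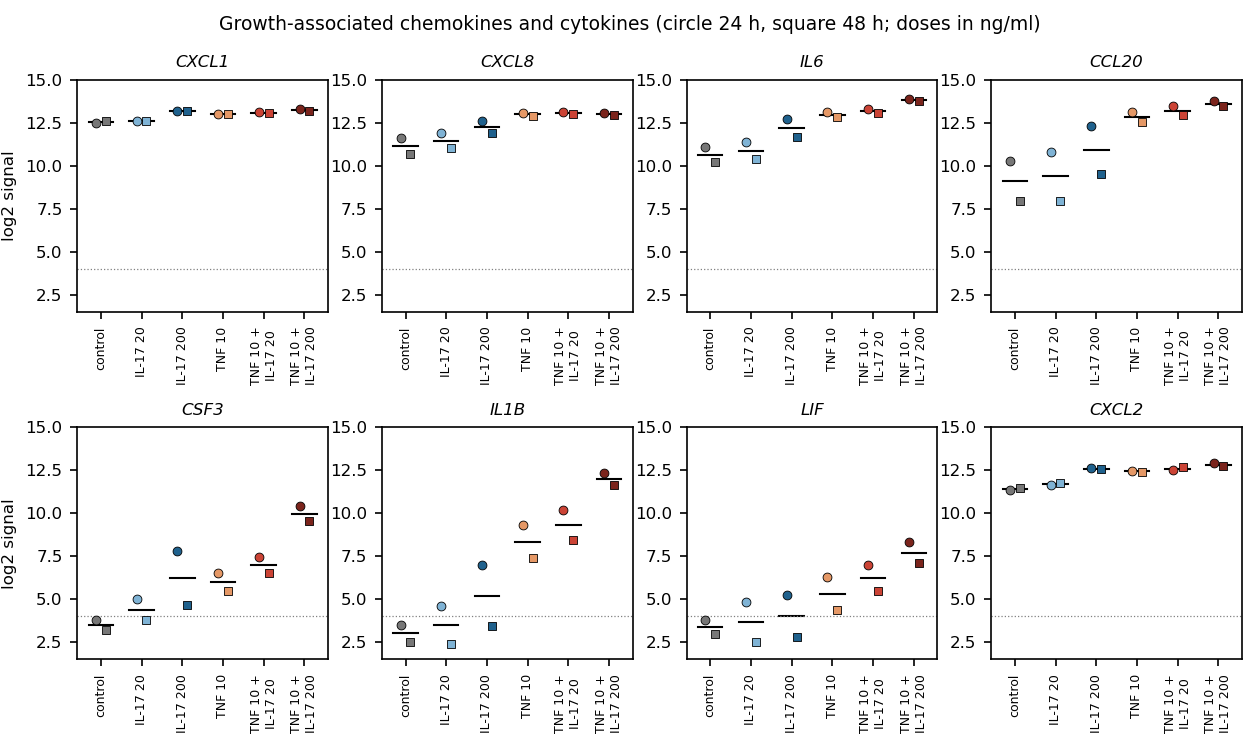
Log2 signal of growth-associated chemokines and cytokines (y axis) by treatment (x axis, doses in ng/ml), 1 array per point, circles at 24 h and squares at 48 h; bars are the mean of both times and the dotted line marks a log2 value of 4. CSF3 reaches 10.4 and 9.53 with TNF and the higher IL-17 dose, against 3.75 and 3.18 in the control arrays.

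Of 28 NF-kB targets, 24 rose with TNF plus IL-17 (26 adjusted over the list alone), and of 38 interferon response genes, 32 did (34 adjusted over the list alone). ICAM1 stood at 2.93 ± 0.08, IDO1 at 3.85 ± 0.22 and CXCL10 at 4.23 ± 0.27. Of 14 IL-17 response genes, 11 rose (12 adjusted over the list alone), among them the elastase inhibitor PI3 at least 7.41-fold and NFKBIZ by 0.47 ± 0.12 (adjusted p = 0.0249). The NFKBIZ call held in 15 of 27 alternatives (adjusted p from 0.00126 to 0.383). It was lost, among others, with the ACTB difference in the fit (0.44 ± 0.24) and without either control (0.35 ± 0.16 and 0.59 ± 0.16), either array of TNF with 20 ng/ml (0.46 ± 0.14 and 0.47 ± 0.14) or the 24 h array of TNF with 200 ng/ml (0.39 ± 0.12). Dedifferentiation genes rose in 13 and fell in 1 of 21 (15 and 2 adjusted over the list alone), led by CCN1 (3.22 ± 0.13) and WNT5A (1.84 ± 0.13). These lists had camera adjusted p of 1.29e-20, 5.95e-20, 1.29e-09 and 2.07e-08 at the preset correlation. They held with an estimated one, at 0.0146, 0.0117, 0.0117 and 0.0117. Class I presentation had 10 of 19 higher (12 adjusted over the list alone; adjusted p = 0.0558 with an estimated correlation). Class II presentation had 1 higher, CTSS (2.40 ± 0.15), and 5 lower, among them HLA-DMA (-0.78 ± 0.11), with 1 and 6 adjusted over the list alone (camera adjusted p = 0.151). Matrix and protease genes had 14 of 26 higher and 2 lower (17 and 2 adjusted over the list alone; adjusted p = 0.0988 with an estimated correlation), with the tenascin gene TNC at 2.00 ± 0.18 and LAMB3 at 1.89 ± 0.12.

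Fibroblast markers had 7 of 14 higher (7 adjusted over the list alone; adjusted p = 0.0869 with an estimated correlation), with PDGFRA at 1.40 ± 0.10 and LOX at 1.74 ± 0.16. Cell cycle genes had 5 of 42 higher (3 adjusted over the list alone; adjusted p = 0.642 with an estimated correlation), among them CCNE2 (1.10 ± 0.21). Apoptosis regulators had 6 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.174 with an estimated correlation). The unfolded protein response had 3 higher and 2 lower (3 and 2 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation), with ATF3 at 1.44 ± 0.10 and CHAC1 at -0.75 ± 0.13. Adhesion genes (4 higher, 3 lower; median 0.18, mean -0.03, camera adjusted p = 0.464) included CDH1 at -2.04 ± 0.13, and cytokine receptors (4 higher, 3 lower; adjusted p = 0.464) included the second TNF receptor TNFRSF1B at 2.14 ± 0.28. Cholesterol synthesis (2 higher, 1 lower, adjusted p = 0.319), the oxidative stress response (3 higher, 3 lower, adjusted p = 0.99) and p53 targets (2 higher, 4 lower, adjusted p = 0.531) had no camera call. Fry called cholesterol synthesis (adjusted p = 0.00837) and p53 targets (adjusted p = 0.042) lower, and not the oxidative stress response (adjusted p = 0.852). ACAT2 stood at -1.71 ± 0.11, HMOX1, the heme-degrading enzyme, at -1.39 ± 0.20 and SESN1 at -0.77 ± 0.12. Of the immune markers, ITGAX (0.74 ± 0.12), FCER1G (0.73 ± 0.11) and LCP1 (1.01 ± 0.17) rose. Of the keratinocyte markers 3 of 20 were tested (KRT10, SFN and PERP) and of the endothelial markers 1 of 14 (FLT1), and none of them passed.

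In all, 2684 genes changed with TNF plus IL-17 (1279 higher, 1405 lower), 451 of the higher and 184 of the lower by at least 2-fold. The ACTB 3' minus 5' difference was 0.47 ± 0.14 and the hybridization control bioB 0.39 ± 0.13 higher than in the control. The count was 471 with the ACTB difference in the fit, 1317 without the 24 h control and 1369 without the 48 h control.

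Pigment genes fell in part. With TNF alone 14 of 34 tested pigmentation genes fell and none rose (16 adjusted over the list alone; camera adjusted p = 4.42e-08), and with TNF plus IL-17 20 fell (24 lower and 1 higher adjusted over the list alone; adjusted p = 1.29e-09). Both held with an estimated correlation, at camera adjusted p of 0.0291 and 0.0225. SLC45A2, a melanosome transporter, fell by 2.00 ± 0.11 with TNF and by 2.76 ± 0.10 with both cytokines. GPR143, a melanosome receptor, fell by 1.05 ± 0.11 and 1.34 ± 0.09, and RAB27A, which carries melanosomes to the cell edge, by 0.84 ± 0.11 and 1.08 ± 0.09. TYR, the rate-limiting enzyme of melanin synthesis, fell by 0.30 ± 0.08 with TNF (adjusted p = 0.0494) and by 0.46 ± 0.07 with both (adjusted p = 0.0023). With the ACTB difference in the fit both calls were lost as the spread grew and the size stayed (-0.31 ± 0.12, adjusted p = 0.273, and -0.47 ± 0.14, adjusted p = 0.12). The call with TNF passed in 9 of 25 alternatives (adjusted p from 0.00106 to 0.619) and was lost, among others, without either control array (0.198 without the 24 h one, 0.219 without the 48 h one) and without either TNF array (0.229 and 0.197). The call with both passed in 24 of 27 (smallest adjusted p 5.98e-06). It was also lost at 24 h alone (-0.42 ± 0.16) and at 48 h alone (-0.50 ± 0.18), each with the doses pooled. Over the alternatives the log2 change of TYR ran from -0.631 to -0.287 with TNF and from -0.968 to -0.315 with both. MITF, the master regulator of the pigment program, stood at -0.22 ± 0.09 with TNF (adjusted p = 0.163) and fell by 0.39 ± 0.08 with both (adjusted p = 0.00721). With TNF it passed in 2 of 25 alternatives, as the mean of its probe sets (-0.59, adjusted p = 0.0138) and with a variance trend (0.0185), in a range up to 0.847. With both it was lost in 6 of 27 (adjusted p from 7.63e-05 to 0.437). It was lost with the ACTB difference in the fit (-0.34 ± 0.15, 0.271), without a time term (-0.39 ± 0.26, 0.437) and at 20 ng/ml (-0.28 ± 0.09, 0.0719). It was also lost at 24 h alone (-0.48 ± 0.15) and at 48 h alone (-0.29 ± 0.14), each with the doses pooled, and without the 24 h control array (-0.31 ± 0.10). The spread was larger in each of the 6, and the size was smaller in 4 of them. MLANA (-0.22 ± 0.07), PMEL (-0.19 ± 0.08) and TYRP1 (-0.14 ± 0.08) did not pass with both cytokines, with adjusted p of 0.0591, 0.116 and 0.258. MLANA passed in 8 of 27 alternatives (adjusted p from 0.00165 to 0.488), for example as the mean of its probe sets (-0.37), PMEL in 1, with a variance trend (0.0142), and TYRP1 in none of 27 (0.0897 or more). Both comparisons share the control arrays. DCT, also in the fixed set of pigment genes, and SLC24A5 were not among the 34 tested.

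**Figure D3:**
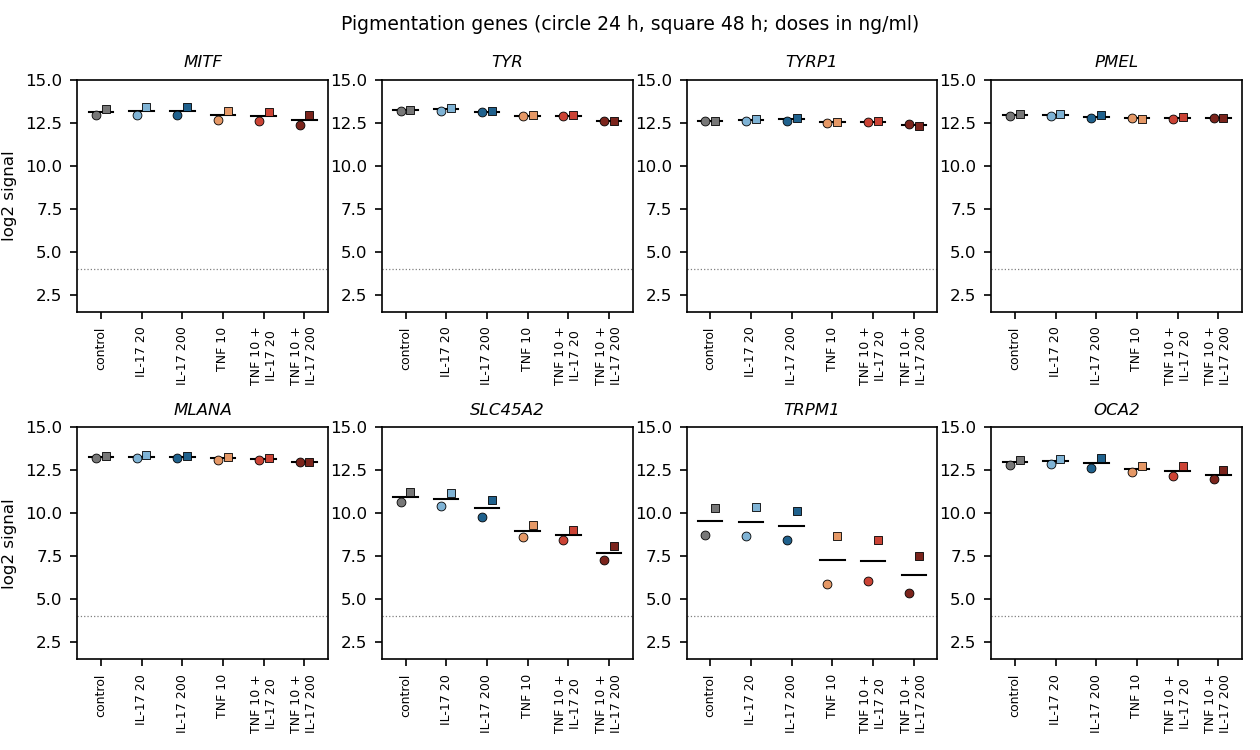
Log2 signal of pigmentation genes (y axis) by treatment (x axis, doses in ng/ml), 1 array per point, circles at 24 h and squares at 48 h; bars are the mean of both times and the dotted line marks a log2 value of 4. SLC45A2 runs from 10.66 and 11.24 in the control arrays to 7.27 and 8.07 with TNF and the higher IL-17 dose, while TYR runs from 13.18 and 13.28 to 12.63 at both times.

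Adding IL-17 to TNF raised a small set of genes above their level with TNF. SERPINB7, a protease inhibitor of epithelia, rose at least 1.93-fold, PI3 by 2.66 ± 0.27 (6.33-fold), LOC100130331 by 2.35 ± 0.19, HSD11B1, a cortisol-regenerating enzyme, at least 1.21-fold, the chaperone clusterin (CLU) by 1.72 ± 0.20, the potassium channel KCND3 by 1.68 ± 0.21, the amino acid transporter SLC7A7 by 1.65 ± 0.24 and the cytokine subunit EBI3 by 1.64 ± 0.19. The falls were LINC02099 (-0.85 ± 0.12), SLC45A2 (-0.76 ± 0.10), DCLK1 (-0.74 ± 0.10) and CD200 (-0.51 ± 0.07). The PI3 call held in 18 of 27 alternatives (adjusted p from 0.0012 to 1) and was lost, among others, without the 48 h TNF array (2.21 ± 0.29, adjusted p = 0.101), without the 24 h array of TNF with 20 ng/ml (2.66 ± 0.31, 0.0589) and with the ACTB difference in the fit (2.68 ± 0.31, 0.061). In all, 31 genes changed (27 higher, 4 lower; 771 at an unadjusted p under 0.05). No growth list member passed over all genes: CSF3 stood at 2.48 ± 0.45 (adjusted p = 0.105), LIF at 1.65 ± 0.32 (0.125), HBEGF at 0.77 ± 0.14 (0.0935) and IL1B at 2.30 ± 0.49 (0.172). Adjusted over the list alone, 6 of 19 rose, and the list as a group was higher (median 0.31, camera adjusted p = 3.78e-10). The IL-17 response list had 3 higher (5 adjusted over the list alone; camera adjusted p = 4.01e-13), PI3, the stromelysin MMP3 (at least 1.12-fold) and the chitinase-like CHI3L1 (adjusted p = 0.000415). CHI3L1 was higher in 2 of 4 pairs and has no fold bound, since it left the floor with 200 ng/ml only. Dedifferentiation genes (1 higher, CCN1 at 0.96 ± 0.13, 3 adjusted over the list alone) and pigmentation genes (1 lower, 1 adjusted over the list alone) also moved as groups, and all 4 lists held with an estimated correlation.

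The remaining lists with a preset call for adding IL-17 to TNF were lost with an estimated correlation, at adjusted p of 0.109 or more. Interferon response genes, for example, had a median of -0.05 and none past the test (adjusted p = 0.262 with an estimated correlation), and of the fibroblast markers PDGFRA rose by 0.65 ± 0.10 (adjusted p = 0.147 with an estimated correlation). The ACTB 3' minus 5' difference was 0.11 ± 0.14, and with it in the fit 7 genes changed. Taken by dose, after the data were seen, adding 200 ng/ml changed 207 genes (167 higher, 40 lower) and adding 20 ng/ml changed 0 by limma (192 at an unadjusted p under 0.05). With the higher dose CSF3 rose by 3.97 ± 0.52 and IL1B by 3.66 ± 0.57 over TNF alone (adjusted p = 0.0106 and 0.0204), and SLC45A2 fell by 1.28 ± 0.11. The count over both doses was 2 without the 48 h TNF array and 7 without the 24 h one. Among arrays of TNF with 20 ng/ml IL-17 it was 7 without the 24 h one and 12 without the 48 h one, and with 200 ng/ml it was 16 and 20. It was 11 without either array of 20 ng/ml IL-17 alone and 14 without either control.

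The interaction asks whether IL-17 acted differently with TNF than without it, on the log2 scale. Only 2 genes passed (312 at an unadjusted p under 0.05). SERPINB7 (2.71 ± 0.12, higher in 4 of 4 pairs) was at the floor of 2.24 in all 8 arrays without both cytokines and reached 6.83 and 6.90 with TNF and 200 ng/ml IL-17. CHI3L1 (1.22 ± 0.10, higher in 2 of 4 pairs) was at the floor except with TNF and 200 ng/ml IL-17, at 4.73 and 4.64. Both sizes are set against the floor. Both genes reached a log2 value of 4 only with TNF and 200 ng/ml IL-17. They thus met the filter through the same values that make the interaction. The CHI3L1 call was lost in 13 of 25 alternatives (adjusted p from 8.07e-05 to 1). With the ACTB difference in the fit it was lost at 1.25 ± 0.12 (adjusted p = 0.0848). It was also lost without either control array (1.23 ± 0.13, 0.0776, and 1.22 ± 0.13, 0.0857), TNF array (1.22 ± 0.13, 0.115, and 1.23 ± 0.13, 0.117) or array of TNF with 20 ng/ml IL-17 (1.23 ± 0.12, 0.0563, and 1.22 ± 0.12, 0.0506). In these 7 the size stayed and the spread grew. With a variance trend it stood at 1.22 ± 0.27 (adjusted p = 0.7), with damped log2 values at 0.33 ± 0.09, and at 20 ng/ml alone at 0. The other 3 pooled the doses. The SERPINB7 call was lost in 4 of 26, those 3 and at 20 ng/ml alone (0.79 ± 0.14). At 200 ng/ml alone, taken after the data were seen, 6 genes passed: SERPINB7, CHI3L1, CD24, HSD11B1, MMP3 and LOC100130331. Over both doses, leaving out the 24 h array of TNF with 200 ng/ml IL-17 gave 4 genes, and leaving out either TNF array or either array of TNF with 20 ng/ml gave 1.

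No member of the growth list passed the log2 interaction. CXCL1 stood at -0.20, CXCL2 at -0.47, CXCL3 at -0.52, CXCL8 at -0.64 ± 0.29, IL6 at -0.40 ± 0.30, CCL20 at -0.47 ± 0.82 and CSF3 at 0.64 ± 0.64, each with an adjusted p of 1. Of the 19 members, LIF (1.17), IL1B (0.95), CSF3 and HBEGF (0.63) stood highest. Leaving out 1 array moved CSF3 to 0.08 (without the 48 h array of 200 ng/ml IL-17), 0.20 (without the 48 h control), 1.08 (without the 24 h control) and 1.20 (without the 24 h array of 200 ng/ml IL-17). CCL20 and IL6 stood at -1.048 and -0.60 without the 24 h TNF array, and at 0.105 and -0.205 without the 48 h one. The list's median was -0.20 and its call was lost (adjusted p = 0.147 with an estimated correlation). Interferon genes (median -0.11; adjusted p = 0.122 with an estimated correlation), pigmentation genes (median -0.10; adjusted p = 0.109 with an estimated correlation) and fibroblast markers (median 0.08; adjusted p = 0.147 with an estimated correlation) lost theirs too. The IL-17 response list had a median of -0.20 but a mean of 0.24, carried by CHI3L1 and 3 more genes higher adjusted over the list alone (4 in all; camera adjusted p = 0.0731). No list kept an interaction with an estimated correlation, and none of MITF (-0.21), TYR (-0.15), MLANA (-0.13), TYRP1 (-0.14) and PMEL (0.08) passed. Additivity was also asked of linear values, as log2 of the combined value over TNF plus IL-17 minus control. Over the 19 growth genes the median was 0.10, with 13 above 0. Over the 3091 genes that lay higher by at least 0.01 with each cytokine alone, a test added after the data were seen found 6 genes above additivity (262 at an unadjusted p under 0.05). They were IL1B (2.23), IL11 (2.11), LOC100130331 (2.08), RGS5 (1.51), SLC7A7 (1.37) and WFDC2 (1.34). This test used 1 value per gene and time, the mean of both doses, with 5.08 prior degrees of freedom. In each of the 6 the excess was larger at 200 than at 20 ng/ml at both times. For SLC7A7 it was 0.35 (24 h) and 0.39 (48 h) at 20 ng/ml, against 2.71 and 2.00 at 200 ng/ml. With other minimum differences from 0 to 0.1 the count was 10 to 19, and CSF3 was among the genes found at each of those but not at 0.01.

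**Figure D4:**
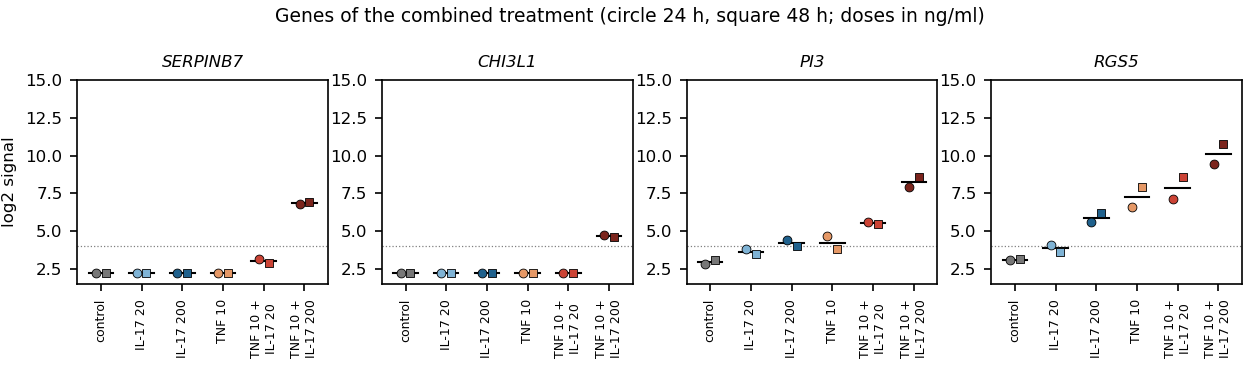
Log2 signal of SERPINB7, CHI3L1, PI3 and RGS5 (y axis) by treatment (x axis, doses in ng/ml), 1 array per point, circles at 24 h and squares at 48 h; bars are the mean of both times and the dotted line marks a log2 value of 4. SERPINB7 lies at 2.24 without both cytokines and at 6.83 and 6.90 with TNF and the higher IL-17 dose.

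The higher IL-17 dose changed 105 genes against the lower one (89 higher, 16 lower; 1237 at an unadjusted p under 0.05). CSF3 rose by 2.43 ± 0.37 (5.38-fold), RGS5 by 2.12 ± 0.31, LOC100130331 by 2.02 ± 0.15, PI3 by 1.64 ± 0.22, IP6K3 by 1.57 ± 0.19, SLC7A7 by 1.54 ± 0.19, KCND3 by 1.45 ± 0.17 and LRRN1 by 1.43 ± 0.12. SLC45A2 (-0.78 ± 0.08) fell most, followed by SMCO3 (-0.75) and HPGD, a prostaglandin-degrading enzyme (-0.61). Of the growth list 6 of 19 rose (13 adjusted over the list alone; camera adjusted p = 1.15e-16), including CCL2 (0.62 ± 0.08), CXCL2 (0.57 ± 0.07) and CXCL6 (0.69 ± 0.12). Of the IL-17 response list 7 of 14 rose (10 adjusted over the list alone; camera adjusted p = 4.36e-16), and of the dedifferentiation list CCN1 did (1.15 ± 0.11; 6 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.41e-05). These 3 lists held with an estimated correlation. Pigmentation genes (1 lower, 2 adjusted over the list alone; adjusted p = 0.0555 with an estimated correlation) and NF-kB targets (3 higher, 6 adjusted over the list alone; adjusted p = 0.0944 with an estimated correlation) did not. Nor did matrix genes (adjusted p = 0.158 with an estimated correlation), class II presentation (adjusted p = 0.147 with an estimated correlation), cell cycle genes (adjusted p = 0.585 with an estimated correlation) and fibroblast markers (adjusted p = 0.0954 with an estimated correlation). CHI3L1 and MMP3, among the 7 IL-17 response genes, were higher in 2 of 4 pairs each. The ACTB 3' minus 5' difference was 0.22 ± 0.11 higher at the higher dose, and 7 genes changed with it in the fit. The count was 14 and 27 without the arrays of TNF with 20 ng/ml IL-17 (24 and 48 h), 20 without the 48 h array of 20 ng/ml alone, and 37 and 26 without those of 200 ng/ml alone. It was 69 and 54 without those of TNF with 200 ng/ml, 49 without either control and 56 without either TNF array.

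Over all 3 matched treatments, arrays with TNF differed from those without in 3871 genes (1623 higher, 2248 lower). IL32 (at least 33.4-fold), IL1B (5.98 ± 0.33), CCL5 (4.70), CXCL11 (4.35), RGS5 (4.11), CXCL10 (4.11), TNFAIP2 (4.06) and COXFA4L3 (3.75 ± 0.11) rose most, in 6 of 6 pairs each. ADCY2 (-2.62 ± 0.18), TRPM1 (-2.46), KCNJ13 (-2.39), SLC45A2 (-2.24 ± 0.07), ITGA9 (-2.24), IL16 (-2.15) and HPGD (-2.10) fell most, and FXYD3 was at least 2.14-fold lower. Of 34 pigmentation genes, 28 fell and 1 rose (29 and 1 adjusted over the list alone). All 19 growth genes (19 adjusted over the list alone), 26 of 28 NF-kB targets (26), 35 of 38 interferon genes (35), 9 of 14 IL-17 response genes (9) and 14 of 19 class I genes (14) rose, and dedifferentiation genes rose in 16 and fell in 2 (18 and 2 adjusted over the list alone). These lists held with an estimated correlation. Matrix genes (14 higher, 3 lower; adjusted p = 0.0988 with an estimated correlation), apoptosis regulators (9 higher, 3 lower; adjusted p = 0.116 with an estimated correlation), fibroblast markers (8 higher, 1 lower; adjusted p = 0.0622 with an estimated correlation) and the unfolded protein response (4 higher, 2 lower; adjusted p = 0.125 with an estimated correlation) did not. The ACTB 3' minus 5' difference was 0.19 ± 0.09 and bioB 0.26 ± 0.09 higher with TNF, and 2329 genes changed with the ACTB difference in the fit.

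Arrays with IL-17 differed from those without in 34 genes (29 higher, 5 lower; 1026 at an unadjusted p under 0.05). CSF3 (2.16 ± 0.32), PI3 (1.81 ± 0.19), the B-cell factor POU2F2 (1.24), LRRN1 (1.05), KCND3 (1.04) and the neurofilament gene NEFM (0.88) rose, and LINC02099 (-0.77), CHDH (-0.61), SLC45A2 (-0.58) and CD200 (-0.42) fell. The count was 1 with the ACTB difference in the fit (0.24 ± 0.10 higher with IL-17) and 0 with the doses pooled. It was 1 without the 48 h TNF array, 14 without the 24 h one, 7 without either control, 14 without the 24 h array of 20 ng/ml alone and 17 without the 48 h array of TNF with 20 ng/ml.

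Time in culture changed 3606 genes, 1813 higher and 1793 lower at 48 h than at 24 h over the 6 treatments. KCNJ13 (2.71 ± 0.14), HPGD (2.32), the hexokinase-like HKDC1 (2.25), TRPM1 (2.06), TNS1 (1.97), NALCN (1.95), PROM1 (1.88) and DOK5 (1.83) rose most. The collagenase MMP1 (-2.78 ± 0.40), the decoy receptor IL13RA2 (-2.05), CEMIP, a hyaluronan-degrading protein (-1.98), THBS1 (-1.93), SCARA5 (-1.91), NEURL1B (-1.90), IL1B (-1.86) and CXCR4 (-1.86) fell most. All 42 cell cycle genes fell (42 adjusted over the list alone, median -0.90), such as the mitotic kinase CDK1 (-0.90), the replication gene MCM6 (-0.83) and NUSAP1 (-0.81 ± 0.05). Their camera adjusted p was 1.37e-23, but the genes moved together (estimated correlation 0.658; adjusted p = 0.147 with an estimated correlation). Of 34 pigmentation genes 20 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 3.12e-09), among them the growth factor receptor KIT (1.27) and SLC24A4 (1.44), and this held with an estimated correlation. Growth genes (11 lower, 12 adjusted over the list alone; adjusted p = 0.0732 with an estimated correlation), dedifferentiation genes (3 higher, 11 lower; adjusted p = 0.0944 with an estimated correlation), NF-kB targets (12 lower; adjusted p = 0.147 with an estimated correlation), matrix genes (1 higher, 11 lower; adjusted p = 0.147 with an estimated correlation) and class I genes (4 higher; adjusted p = 0.174 with an estimated correlation) lost their preset call. The ACTB 3' minus 5' difference was 0.26 ± 0.09 and bioB 0.27 ± 0.09 higher at 48 h, and 885 genes changed with the ACTB difference in the fit. Any handling that differed between the 24 h and 48 h cultures cannot be told apart from time.

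The effect of TNF differed between the times for 98 genes (signed effect higher at 48 h for 52 and lower for 46), and that of IL-17 for 0 genes by limma (191 at an unadjusted p under 0.05). Of the 46, 34 lay lower with TNF at 48 h, and for 28 the effect was larger in size at 48 h than at 24 h. Among the 52, the difference was 2.48 for CEMIP, 2.24 for MMP1 and 2.17 for CCL20, a chemokine for lymphocytes. Without either array of TNF with 20 ng/ml IL-17 the count for TNF was 10, without either control 13, without either array of TNF with 200 ng/ml 14, without either TNF array 21 and without either array of 20 ng/ml IL-17 alone 41. The count for IL-17 was 1 without either TNF array.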

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

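The tests of explanations and the splits of the arrays in this part were all chosen after the results were seen. The differences themselves came from comparisons set before the data were examined.

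A difference between the times was found for TNF. Its effect at 48 h minus that at 24 h passed the test for 98 genes. With its sign counted, the effect was higher at 48 h for CEMIP (2.48 log2 units), the collagenase MMP1 (2.24), CCL20 (2.17), UCN2 (1.87), LINC00973 (1.75), the early response factor EGR1 (1.70), the sterol hydroxylase CH25H (1.70) and IL11 (1.69). It was lower for STON1 (-2.13), GPR84 (-2.10), OR7A5 (-1.98), CDK15 (-1.83), PRELP (-1.67), XG (-1.62), TAGLN (-1.59) and BCAN (-1.58). Lower does not mean smaller: of the 46 genes with a lower term, 34 lay lower with TNF at 48 h and 28 had an effect larger in size at 48 h (median effect 0.03 at 24 h and -0.80 at 48 h). OR7A5, XG and BCAN stood under a log2 value of 4 in every array with TNF, and GPR84 in every array without TNF. STON1 did so in every 24 h array, TAGLN in every 48 h array, IL11 in the 48 h arrays without TNF and CDK15 in the 24 h arrays with TNF. The sizes for these 8 genes rest in part on background. The count was 10 without either array of TNF with 20 ng/ml IL-17, 13 without either control, 14 without either array of TNF with 200 ng/ml, 21 without either TNF array and 41 without either array of 20 ng/ml IL-17 alone. The 6 pairs of arrays make only 10 splits into groups of 3, too few for a share under 0.05 (1 of 10 reached the real count of 98, and the highest other gave 0).

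For the 52 genes with a higher effect at 48 h, a ceiling of the signal with TNF at 24 h stays open. Of these genes, 27 read at least 0.5 above their mean level with TNF at 24 h in some array, and 25 did not. That array can itself be among those with TNF at 24 h, so the counts decide nothing. Of all 52 genes, 6 had a mean level of 12 or more with TNF. RNA quality cannot be told apart: the ACTB 3' minus 5' difference hardly differed in this contrast (-0.04 ± 0.21), so a median of 1.01 with it in the fit and 1.02 without it decides nothing, and 52 genes passed with it, 27 of them among these. Between 24 and 48 h their median change was -1.38 without TNF and -0.23 with it (51 of 52 fell without TNF), and for the 46 genes with a lower effect it was 1.02 and 0.03 (39 rose without TNF). These genes were picked by the difference itself, so such medians describe it and test no explanation. Handling at each time and an effect of TNF on genes that change in culture stay open, untested.

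A difference in the TNF effect with and without IL-17 was found for SERPINB7 (2.71) and CHI3L1 (1.22). Both lay at the floor without both cytokines, so their spread in those arrays is fixed by the floor and their p rests on the spread of other genes. Both also met the filter only through the arrays with TNF and 200 ng/ml IL-17.

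Probe sets without a gene symbol lay outside the comparisons of genes. Of 2424 tested, 529 changed with TNF present, 276 higher and 253 lower.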

How the results depend on the processing

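The fits at a single IL-17 dose, with the ACTB 3' minus 5' difference as a covariate, and of linear additivity over all genes were chosen after the data were seen, and the others before. Over all alternatives, the named genes kept direction and side of the threshold in 5227 cases, lost the threshold in 909, newly passed it in 48 and reversed in 17. The medians of the gene lists kept their direction in 692 cases, with 2 weaker and 0 reversed, and the list tests stayed in 89 and weakened in 59. The labels carry no replicate numbers, so no block by number was fitted, and arrays were matched by time through the time term. The cause of a shift was not tested unless a smaller number of genes, arrays or doses accounts for it by construction. Signal near the floor limits what can be seen: genes without a log2 value of 4 in at least 2 arrays were not tested.

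With no filter on low values, 823 genes changed with TNF alone, 2 with IL-17 alone, 13 on adding IL-17 to TNF, 6 in the interaction, 13 by dose and 13 with IL-17 present, and the effect differed by time for 9 (TNF) and 1 (IL-17). With a filter at a log2 value of 6 the counts were 4 for IL-17 alone, 1 for the interaction and 62 for IL-17 present. The mean of a gene's probe sets gave 2 for IL-17 alone and 65 for IL-17 present, and MLANA with IL-17 alone was 0.017. A further quantile normalization gave 4 for IL-17 alone. The damped log2 gave 2 for IL-17 alone, 1 for the interaction and 65 for IL-17 present. A variance trend gave 14 for IL-17 alone, 49 for adding IL-17, 1 for the interaction, 179 for dose, 101 for IL-17 present and 168 for TNF by time.

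With the doses pooled, limma found 0 for adding IL-17, 0 for the interaction, 0 for IL-17 present and 31 for TNF by time. Without a time term the counts were 285 (TNF alone), 945 (TNF plus IL-17), 9 (adding IL-17), 3 (dose), 2040 (TNF present) and 3 (IL-17 present). The fits of the 24 h or 48 h arrays alone, given next, also pooled the doses. Their shifts therefore cannot be put down to the time alone. The 24 h arrays alone gave 25 (TNF alone), 141 (TNF plus IL-17), 0 (adding IL-17), 0 (interaction), 928 (TNF present) and 0 (IL-17 present), with MITF at -0.017 for IL-17 alone and CSF3 at -0.252 for the interaction. The 48 h arrays alone gave 3, 223, 0, 0, 1356 and 0 in that order, with TYR at 0.002 for IL-17 alone. With only the treatments compared, 333 genes changed with TNF alone and 17 by dose. A 2-fold minimum left 422 (TNF alone), 635 (TNF plus IL-17), 15 (adding IL-17), 26 (dose), 476 (TNF present), 7 (IL-17 present), 252 (time) and 50 (TNF by time). Array weights gave 2018 (TNF alone), 48 (adding IL-17), 4 (interaction), 43 (dose), 64 (IL-17 present) and 912 (TNF by time).

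At 200 ng/ml IL-17 alone the counts were 21 (IL-17 alone), 207 (adding IL-17) and 6 (interaction). At 20 ng/ml they were 1490 (TNF plus IL-17), 0 (adding IL-17) and 0 (interaction), with MLANA at 0.014 and TYR at 0.058 for IL-17 alone and CCL20 at 0.09 and CXCL1 at 0.008 for the interaction. With the ACTB difference in the fit, 329 (TNF alone), 471 (TNF plus IL-17), 7 (adding IL-17), 1 (interaction), 7 (dose), 2329 (TNF present), 1 (IL-17 present), 885 (time) and 52 (TNF by time) were left. In additivity of linear values, CCL20 was 0.377 and IL6 0.242 above the sum, against log2 interactions of -0.47 and -0.40, and 6 genes passed (10 to 19 at other minimum differences with each cytokine alone).

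Leaving out each array gave 515 to 1432 genes for TNF alone, 0 to 2 for IL-17 alone, 1317 to 2908 for TNF plus IL-17, 2 to 23 for adding IL-17, 1 to 4 for the interaction and 14 to 80 for dose. It gave 3006 to 3962 for TNF present, 1 to 36 for IL-17 present, 2704 to 3453 for time, 10 to 87 for TNF by time and 0 to 1 for IL-17 by time. The report names the arrays behind each shift over 1.5 times. For IL-17 alone, MITF ranged from -0.036 (without the 48 h control) to 0.121, MLANA from -0.016 to 0.013 (without the 48 h control or the 24 h array of 20 ng/ml) and TYR from -0.02 to 0.011, with 0.008 without the 48 h control. The CCL20 interaction ranged from -1.048 to 0.105 (without the 48 h TNF array), with 0.004 without the 48 h control. The lone array left of a treatment was assumed to vary like the others.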

Other observations

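All tests of explanations and all splits of the arrays in this part were chosen after the results were seen. The splits were counted in 3 ways (every split, splits that pose the identical test passed over, and main terms only), and the values below count every split unless said otherwise.

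No chemokine or cytokine of the growth list passed the log2 interaction. On linear values IL1B passed above additivity (2.23, adjusted p = 0.0335), and CSF3 did at 4 other minimum differences and LIF at 1 of them. Their log2 interactions were above 0 as well (0.95, 0.64 and 1.17). The linear test covered fewer genes and had its own estimate of the spread, so scale and test cannot be told apart. On simulated data the log2 interaction test recovered 8% of genes at a change of 0.5 and 78% at 1. Over the list the median of 0.10 (SE of the mean 0.17) covers members that went both ways, so for the list as a whole the scale cannot be told apart from spread. A common ceiling of the array signal, whose maxima were 15.24 to 15.51, is argued against for the members at low levels with both cytokines. They were CSF1 (5.14), HBEGF (6.43), KITLG (6.83), LIF (6.97), FGF2 (7.19), EREG (7.75) and CSF3 (8.47). For the other members, at 10.22 (CCL5) to 13.5 (IL6), it stays open. Saturation of the response in the cells stays open for all members.

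All 42 cell cycle genes were lower at 48 h than at 24 h. RNA quality is argued against as the whole cause, since the list's median was -0.85 with the ACTB difference in the fit and -0.90 without it. A change in TNF arrays alone is argued against by a median of -1.11 without TNF (-0.70 with it). By treatment the medians ran from -1.24 (20 ng/ml IL-17) to -0.44 (TNF with 200 ng/ml). A scaling of all genes cannot be told apart, since the quantile step had set the arrays to nearly equal medians, and the median of 0.003 over all tested genes follows from it. Crowding of the cells was not tested, and a batch of the 48 h cultures cannot be told apart from time.

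Among splits of the arrays, the real count for TNF present was 3871, and the highest other split also gave 3871. Only 3 of 100 splits gave as many, and the 2 besides the real one pose the identical test. With those passed over the highest other gave 0. With main terms only the real count was 4296 and the highest other 1707. For time the real count was 3606 (highest other 0, 1 of 100) and for dose 105 (highest other 1, 1 of 33). A split that poses another test leaves the real effect in the spread, which lowers its count. These shares therefore do not exclude chance. For IL-17 present 6 of 100 splits gave the real count of 34, and the highest other also gave 34. There 5 pose the identical test. With them passed over the highest other gave 3, and 1 of 100 splits, the real one, reached 34. Chance is excluded for neither TNF present nor IL-17 present. For IL-17 present with main terms only, the real count was 0 by limma and the highest other 373. That fit leaves out the dose and interaction terms. Which split gave 373 was not examined, so its source is not known. For IL-17 by time the real count of 0 by limma (191 at an unadjusted p under 0.05) was reached by 32 of 32 splits.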
